A study of Mus musculus with 6 samples.

How the data were processed

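The data are microarray measurements of total RNA from the soleus, a hindlimb muscle rich in slow and fatty acid burning fibres, of male mice aged 18 weeks that had fasted for 14 h. The control mice (WT) carried Gna13 alleles flanked by loxP sites, and the knockout mice (MKO) carried the same alleles with Cre recombinase under the muscle creatine kinase promoter. Each group had 3 mice, and each mouse had 1 array. The replicates were separate animals per the labels.

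Per the labels' protocols, RNA was extracted with TRIzol, amplified and labelled with biotin for whole-transcript arrays, and hybridised to an Affymetrix Mouse Gene 2.0 ST array. The deposited values are log2 values that the authors made by robust multi-array averaging (RMA), per the submitters' processing notes in Affymetrix Expression Console. RMA subtracts background, normalizes between arrays and summarises the probes of each probe set. The versions, the genome build and the annotation release are not given in the sources used here. The series' design text speaks of an export at the level of genes, but the deposited table held 269751 rows with several rows per gene, so it was treated as a table of exon-level probe sets. A probe set of this kind rests on few probes, and its value is noisier than that of a gene.

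Genes were named through the platform's annotation, which is old. Of the rows, 233753 had exactly 1 gene symbol, 5106 had several and 30892 had none, and only the first kind was used for genes. Of the 23152 gene symbols, 20875 were also current symbols in a RefSeq gene table of assembly GRCm38.p6, 2274 were older names there and 3 were not found. Symbols are printed as the array annotation gives them. A gene's value on an array was the mean of the log2 values of its probe sets, with a median of 8 probe sets per gene and 1 probe set for 2319 genes. Positions are not printed because no source used here names the build.

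The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the level), MKO minus WT, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All p-values in the text come from limma and its set tests unless another tool is named. An exact permutation test of 3 against 3 mice cannot give a two-sided p below 0.1. The number of arrays limits the precision. The authors named a local pooled error (LPE) test per the labels. Its package was not installed, and it estimates error from genes of like level without regard to a gene's own spread, so a re-implementation after its published description served as an alternative.

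Gene lists and cell type marker lists were written from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for naming genes. Of 743 entries in the gene lists, 707 matched a tested gene by symbol, 10 by a synonym, 2 repeated a gene already matched and 24 matched none. Of 136 marker entries, 120 matched by symbol, 2 by a synonym, 1 was a repeat and 13 matched none. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 28 gene lists and separately over 12 marker lists. The erythroid list had too few measured genes and was not tested. The result of 1 of the 28 gene lists is not reported here. The preset correlation gives small p-values when the genes of a list vary together between mice, so an estimated correlation was run as an alternative, as was the rotation test fry.

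Named genes were Gna13, the 10 largest rises and the 10 largest falls, up to 4 members per gene list and up to 3 markers per marker list with the smallest p. The rises and falls were to be genes past the adjusted threshold whose 3 MKO arrays did not overlap the 3 WT arrays and whose mean level lay above the median gene. As none passed, both sets were filled with genes meeting the other conditions at an unadjusted p under 0.01. Predicted genes, olfactory and vomeronasal receptors and small RNA genes were counted but not named.

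The other alternatives were limma without the variance trend, with robust moderation, with array weights or with the replicate number as a block, quantile normalization or median centring of the gene values, only genes above the median level, the median instead of the mean of a gene's probe sets, every row tested by itself, and each array left out in turn. Chosen after seeing the data were the use of probe sets above the median level only, quantile normalization without MKO replicate 1, and quantile normalization with an estimated correlation. Tables were prepared and figures drawn with Python 3.11.15.

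The fits were tested on simulated data with the levels and spread of the 23152 genes. Each gene was drawn with its own unmoderated residual SD, which few arrays estimate imprecisely. Spread may therefore vary more between simulated genes than between real ones, and the counts for both tests depend on it. For the comparison of MKO with WT, limma recovered 34 of 50 genes simulated with a log2 change of 1.5, 26 of 50 at a change of 1, 1 of 50 at 0.5 and 0 of 50 at 0.25, and called 1 of 22921 genes simulated without a change. The LPE test recovered 49, 39, 1 and 0 of 50, and called 104 of the 22921 genes without a change. In a simulation of list tests with the genes varying independently, camera called 1 of 1 list shifted by 0.2 and 0 of 27 lists that were not.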

Results

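RNA levels were measured in the soleus of 3 WT and 3 MKO mice to find the transcripts that differ when the G protein subunit Gα13, encoded by Gna13, is deleted in skeletal muscle. The median probe set value per array lay between 4.87 and 4.95 on the log2 scale. Arrays correlated with a mean Pearson r of 0.986 ± 0.0024 (SD of 3 pairs) within WT, 0.980 ± 0.0031 (SD of 3 pairs) within MKO and 0.983 ± 0.0025 between the groups, over all genes, which are not independent replicates. The first principal component, with 32.8% of the variance, set MKO replicate 1 apart at 33.6, against −19.7 to 14.4 for the other arrays, and the second, with 20.5%, set MKO replicate 2 apart at 31.4, against −12.8 to 1.09.

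Gna13 was examined first as a check of the genotype. One of its 7 probe sets, 17257825, was lower in MKO, at 4.0 ± 0.50 against 5.96 ± 0.41 in WT (SD, n = 3), a log2 fold change of −1.95 (SE 0.42) or a 3.87-fold lower value. Its adjusted p over the 7 probe sets was 0.00335, and every MKO array lay below every WT array. Of the other probe sets, 3 were higher in MKO. Probe set 17257829 differed by 0.67 (SE 0.13, adjusted p = 0.00335), 17257828 by 0.51 (SE 0.13, adjusted p = 0.00854) and 17257824 by 0.65 (SE 0.20, adjusted p = 0.0149). The last missed the threshold without WT replicate 3 (adjusted p = 0.0566) or without MKO replicate 2 (0.0581), and both it and 17257828 missed it without a variance trend (0.0526 and 0.0799) and by the LPE test (0.252 and 0.226). Over their alternatives the adjusted p ranged from 0.00964 to 0.252 for 17257824, from 0.00501 to 0.226 for 17257828 and from 0.00234 to 0.0466 for 17257829. The remaining 3 probe sets, 17257823, 17257826 and 17257827, differed by −0.37 (SE 0.34), 0.55 (SE 0.53) and 0.23 (SE 0.19), none past the threshold. The mean over the 7 probe sets was 6.73 ± 0.20 in WT and 6.77 ± 0.14 in MKO (SD, n = 3), a difference of 0.04 (SE 0.13, adjusted p = 0.9997 over all genes) that turned to −0.06 without WT replicate 1 and −0.03 without MKO replicate 3, and that was 0.65 for the median of the probe sets. Which exon each probe set reads is not given in the sources used here, so a probe set outside the deleted part checks nothing. Adjusted over all rows of the table instead of the 7 Gna13 probe sets, the fall of 17257825 did not pass (adjusted p = 0.977, and 0.00293 at the lowest over its other alternatives).

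**Figure D1:**
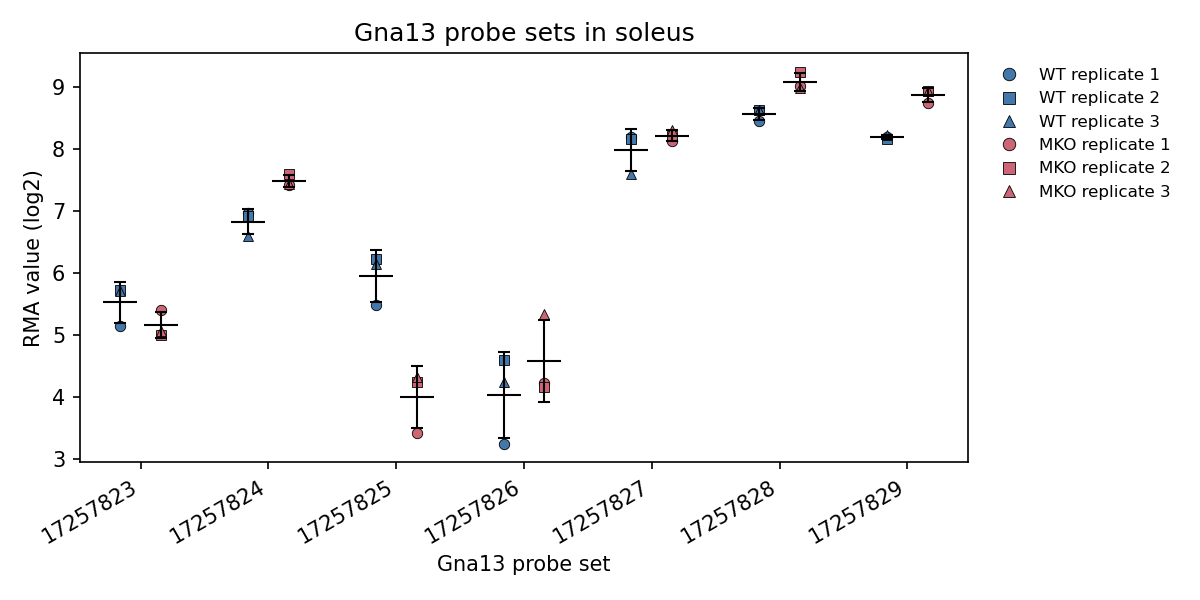
RMA values (log2) of the 7 Gna13 probe sets on each array, with group means and SD (n = 3) as black lines. Probe set 17257825 averaged 5.96 in WT and 4.0 in MKO, while 17257824, 17257828 and 17257829 were higher in MKO by 0.51 to 0.67.

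No single gene passed the adjusted threshold. Rrad, a small GTPase that inhibits voltage-gated calcium channels, had the lowest p. It stood at 6.19 ± 0.19 in MKO against 7.43 ± 0.33 in WT (SD, n = 3), a log2 fold change of −1.24 (SE 0.16, 2.36-fold lower, adjusted p = 0.0917). Nr4a2 (−1.02, SE 0.30) and Nr4a1 (−0.62, SE 0.13), nuclear receptors of the immediate early response, also ranked among the 10 largest falls. Nr4a2 ranged from 5.38 to 7.06 in WT, with a highest MKO value of 5.34, and its difference was −0.61 without WT replicate 3. The same set held Tfrc, the transferrin receptor that takes up iron (−0.80, SE 0.14), the prostaglandin E2 receptor gene Ptger4 (−0.83, SE 0.21) and the embryonic myosin heavy chain Myh3 (−0.70, SE 0.15). Its vascular members were Apold1 (−0.73, SE 0.16), an early response gene of endothelium, and Cldn5, an endothelial tight junction protein (−0.73, SE 0.15). Ces5a (−0.64, SE 0.17) and the semaphorin gene Sema6a (−0.64, SE 0.15) completed it.

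Among the 10 largest rises, Cpt1b, the muscle enzyme that commits long-chain fatty acids to mitochondrial import, stood at 8.71 ± 0.21 in MKO against 8.13 ± 0.11 in WT (SD, n = 3), a difference of 0.58 (SE 0.11) that rests on 1 probe set. Hfe, a regulator of iron uptake (0.77, SE 0.23), and Slc40a1, the iron exporter ferroportin (0.54, SE 0.17), were higher, opposite in sign to Tfrc. The largest rise was that of Ppapdc1a, a lipid phosphatase gene now named Plpp4 (0.93, SE 0.17, 1.91-fold higher, adjusted p = 0.586). Gbp10, an interferon-inducible GTPase, differed by 0.69 (SE 0.12), and Fnip2, a folliculin partner, by 0.58 (SE 0.16). The others were the homeobox gene Hoxa11 (0.59, SE 0.17), the histone gene Hist2h2be (0.55, SE 0.16), Srp54a of the signal recognition particle (0.53, SE 0.18, 1 probe set) and the secreted factor Wnt4 (0.49, SE 0.15). WT means of Ppapdc1a, Hoxa11, Fnip2, Hist2h2be and Wnt4 (4.06, 4.15, 4.75, 4.41 and 4.70) lay below the arrays' median probe set value (4.87 to 4.95). In all 20 genes the 3 MKO arrays lay apart from the 3 WT arrays, as the naming rule required.

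**Figure D2:**
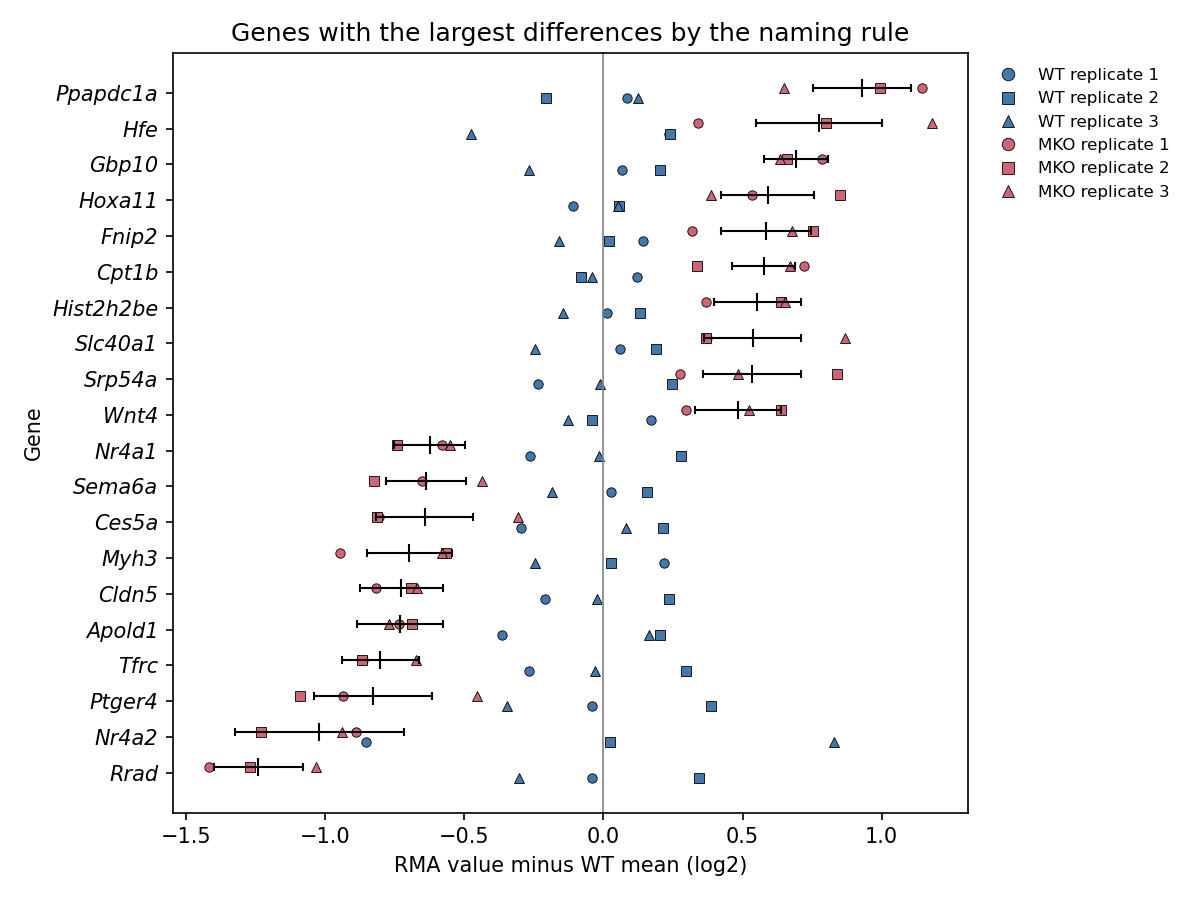
RMA values minus the WT mean (log2) on each array for the 10 genes with the largest rises and the 10 with the largest falls by the naming rule. Black bars show the MKO minus WT difference with its SE (n = 3), from 0.93 for Ppapdc1a to −1.24 for Rrad, and none of the 20 genes passed an adjusted p of 0.05.

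With limma, 0 of 23152 genes were higher and 0 lower in MKO at an adjusted p under 0.05. At an unadjusted p under 0.05, 444 genes were higher and 558 lower, together 1002, where 1157.6 are expected by chance. Median centring of the arrays turned that split to 545 higher and 354 lower. With a fold of at least 1.5 in addition, 95 were higher and 70 lower, counts that reached 198 and 165 without MKO replicate 3, 178 and 134 without MKO replicate 1, and 293 and 262 for the median of probe sets, and that were 13 and 28 for genes above the median level. The 3 MKO arrays lay apart from the 3 WT arrays for 9.25% of genes, and chance gives 10% for 3 against 3. The re-implemented LPE test, which called genes simulated without a change, called 7 genes higher and 16 lower. Its smallest p was that of Myh4, whose arrays overlapped between the groups, as did those of 15 of the 23 genes in all. Rrad, Tfrc, Cpt1b, Nr4a2, Apold1 and Ces5a were among the 8 whose arrays lay apart. In simulated data, limma recovered 26 of 50 genes with a log2 change of 1 and 1 of 50 with a change of 0.5. With an array left out, the calls were Rrad without WT replicate 3 (adjusted p = 0.0365) and 1 dim immunoglobulin kappa variable segment, higher without WT replicate 1 (adjusted p = 0.0152).

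Genes of fatty acid use were higher in MKO as a group. Of 31 measured genes of fatty acid uptake and beta-oxidation, 23 were higher, with a median log2 fold change of 0.07 (camera adjusted p = 1.92e-05, adjusted p = 0.381 with an estimated correlation). Cpt1b passed when adjusted over the list alone (adjusted p = 0.00669), the 1 member of this list to do so. Ucp3, an uncoupling protein of muscle mitochondria (0.41, SE 0.17), the acyl-CoA thioesterase Acot2 (0.25, SE 0.10) and Pdk4, a kinase that limits glucose oxidation (0.16, SE 0.06), did not. Of 17 lipid droplet and lipolysis genes, 13 were higher, with a median of 0.09 (adjusted p = 0.0123, adjusted p = 0.381 with an estimated correlation). Plin5, a coat protein that tethers lipid droplets to mitochondria, stood at 7.86 ± 0.02 in MKO against 7.40 ± 0.07 in WT (SD, n = 3), a difference of 0.46 (SE 0.10) that passed when adjusted over the list alone (adjusted p = 0.00635). Dgat2 (0.20, SE 0.09), Plin3 (0.23, SE 0.11) and Lipe (0.17, SE 0.12) did not. The lipid droplet list missed the threshold without WT replicate 2 (adjusted p = 0.108), without MKO replicate 2 (0.106) and without a variance trend (0.0904). Over 18 alternatives the adjusted p ranged from 1.79e-10 to 0.381 for the fatty acid list and from 0.0017 to 0.381 for the lipid droplet list.

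After quantile normalization of the gene values, 5 gene lists were higher and 4 lower, against 2 higher and 8 lower in the deposited values. With quantile normalization and an estimated correlation, 0 lists passed. At the preset correlation the median of the fatty acid list was then 0.11 (adjusted p = 1.79e-10, 0.149 with an estimated correlation) and that of the lipid droplet list 0.14 (adjusted p = 0.0017, 0.337 with an estimated correlation). Respiratory complexes II to IV and ATP synthase had a median of 0.02 in the deposited values (25 of 38 genes higher, adjusted p = 0.129) and 0.06 after quantile normalization (adjusted p = 0.00104, 0.149 with an estimated correlation), and in the deposited values they passed for genes above the median level (0.0487). The members with the smallest p went both ways, with Uqcrb (0.70, SE 0.24, 1 dim probe set) and Atp5g3 (0.34, SE 0.13) higher and Cox6a2 (−0.18, SE 0.07) and Atp5g1 (−0.38, SE 0.15) lower. Atp5g3 turned to −0.0374 with the median of its probe sets. The tricarboxylic acid cycle list went from 0.02 (adjusted p = 0.275) to 0.07 (adjusted p = 0.00309, 0.337 with an estimated correlation) and the regulators of mitochondrial biogenesis from 0.01 (adjusted p = 0.157) to 0.05 (adjusted p = 0.0302, 0.337 with an estimated correlation), with no member of either past an unadjusted p of 0.05. In the deposited values the biogenesis list passed without MKO replicate 2 (adjusted p = 0.0310), for genes above the median level (0.0409) and with bright probe sets only (0.0145), and its median changed sign to −0.04 without MKO replicate 3. Respiratory complex I did not pass in either form (adjusted p = 0.751 and 0.0699), and its deposited median of 0.02 and mean of −0.01 differed in sign.

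Genes of the extracellular matrix were lower in MKO, 30 of 32, with a median log2 fold change of −0.22 (adjusted p = 2.07e-07, adjusted p = 0.381 with an estimated correlation). The arrays overlapped in the mean of this list relative to the WT mean. In the deposited values WT replicate 3 (−0.19) lay below MKO replicates 2 (−0.07) and 3 (−0.15), with MKO replicate 1 at −0.36. The collagen cross-linking enzyme Lox (−0.51, SE 0.16), the protease Mmp2 (−0.32, SE 0.12), Thbs4 (−0.27, SE 0.12) and Col6a2 (−0.26, SE 0.12) had the smallest p, none past the threshold over the list alone. Without MKO replicate 1, which had the lowest mean of this list and of the fibroblast markers, the median was −0.11 (adjusted p = 0.0164). Markers of fibroblasts and fibro-adipogenic progenitors (median −0.20) and of tenocytes (−0.12) were lower along with the matrix genes at the preset correlation. The matrix list shares genes with both, among them Col1a1 with the fibroblast and Thbs4 with the tenocyte markers, so part of this is built in. In the deposited values WT replicate 3 had the lowest tenocyte mean of all arrays (−0.35). Its fibroblast mean (−0.16) lay below MKO replicates 2 (−0.07) and 3 (−0.12). With an estimated correlation neither marker list passed (camera adjusted p = 0.565 and 0.578). Immediate early genes, which respond within minutes to contraction and other stimuli, were lower with a median of −0.16 (15 of 23 lower, adjusted p = 0.000909, adjusted p = 0.381 with an estimated correlation). Adjusted over the list alone, 4 were lower: Nr4a1, Nr4a2, Fosl2 (−0.50, SE 0.14) and Junb (−0.41, SE 0.12). The immediate early list missed the threshold without WT replicate 2 (adjusted p = 0.0664). The interferon response list had a median of −0.18 (18 of 23 lower, adjusted p = 0.00201, 0.381 with an estimated correlation), led by Rsad2 (−0.58, SE 0.18), Stat2 (−0.42, SE 0.16), Xaf1 (−0.63, SE 0.30) and Ifit2 (−0.51, SE 0.25). Of the 10 Rsad2 probe sets, 17280330 stood at −4.12 (SE 0.54), which weighs on the gene's mean. Heat shock proteins had a median of −0.11 (21 of 23 lower, adjusted p = 0.00162, 0.381 with an estimated correlation), with the chaperone partner Bag3 at −0.23 (SE 0.07), Dnajb5 at −0.28 (SE 0.12), Dnaja1 at −0.40 (SE 0.17) and the mitochondrial chaperone Hspd1 at 0.20 (SE 0.09). Of the 15 Dnaja1 probe sets, 17412792 stood at −2.66 (SE 0.39). With the median of probe sets Dnaja1 turned to 0.0233 and Hspd1 to −0.0028. Without MKO replicate 1 neither the interferon list (adjusted p = 0.0844) nor the heat shock list (0.151) passed, and the heat shock list also missed the threshold without WT replicate 2 (0.0664). In the deposited list means, WT replicate 3 lay below MKO replicate 3 for interferon genes (−0.13 against −0.06). The same held for heat shock proteins (−0.05 against 0.02). For immediate early genes every MKO array lay below every WT array, but not after quantile normalization (highest MKO minus lowest WT −0.0188 and 0.112). Over 18 alternatives the highest adjusted p of these 4 lists lay between 0.381 and 0.442, and the lowest between 8.16e-14 and 0.000195.

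Contractile genes of both fibre types were lower as lists. Slow fibre genes had a median of −0.05 (13 of 18 lower, adjusted p = 0.00381, adjusted p = 0.381 with an estimated correlation). Myl6b, a slow and embryonic myosin light chain, was lower by the list alone (−0.48, SE 0.09, adjusted p = 0.00266), while Tpm3 (−0.31, SE 0.10), Myh7b (−0.39, SE 0.13) and Csrp3 (−0.21, SE 0.09) did not pass. The list missed the threshold after quantile normalization (median −0.01, adjusted p = 0.0683), without a variance trend (0.0581), without WT replicate 3 (0.0847) and without MKO replicate 2 (median 0.01, adjusted p = 0.224). Fast fibre genes had a median of −0.09 (13 of 18 lower, adjusted p = 0.0289, adjusted p = 0.583 with an estimated correlation). The type IIb myosin heavy chain Myh4 stood at 8.19 ± 3.21 in MKO against 10.70 ± 1.13 in WT (SD, n = 3), and its value in MKO replicate 1 was 5.11. Casq1 (−0.24, SE 0.11), Mylpf (−0.22, SE 0.12) and Pvalb (−0.64, SE 0.45) followed. Without MKO replicate 1 the median of the fast fibre list turned to 0.03 (adjusted p = 0.604), and it also missed the threshold without WT replicate 1 (0.0665) and after quantile normalization (0.2502). The slow and fast myosins Myh7, Myh2 and Myh1 differed by −0.10 (SE 0.08), −0.09 (SE 0.08) and 0.08 (SE 0.18). The adjusted p ranged from 7.91e-05 to 0.421 for the slow fibre list and from 6.63e-05 to 0.620 for the fast fibre list over their alternatives.

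Proteasome subunits had a median of −0.09 (25 of 31 lower, adjusted p = 0.00381, adjusted p = 0.549 with an estimated correlation), with Psmb2 at −0.43 (SE 0.13), Psmb5 at −0.23 (SE 0.11), Psmd11 at −0.27 (SE 0.14) and Psmb4 at 0.23 (SE 0.12). Of the 9 Psmb2 probe sets, 17418634 stood at −2.44 (SE 0.36). With the median of probe sets Psmb2 turned to 0.379 and Psmb4 to −0.120. Genes of polyamines, calcium handling and excitation had a median of −0.10 (19 of 24 lower, adjusted p = 0.0113, adjusted p = 0.549 with an estimated correlation), with the calcium channel subunit Cacnb1 at −0.27 (SE 0.10), Odc1 at −0.23 (SE 0.11), Clcn1 at −0.20 (SE 0.11) and Kcnn3 at −0.28 (SE 0.17). Both lists missed the threshold after quantile normalization (adjusted p = 0.0683 for each) and without MKO replicate 1 (0.202 and 0.687). The proteasome list also did so without WT replicate 2 (0.0972), and the other list without WT replicate 1 (0.126). The adjusted p ranged from 6.63e-05 to 0.549 and from 0.000105 to 0.687 over their alternatives. Without MKO replicate 1, 3 gene lists were lower instead of 8.

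**Figure D3:**
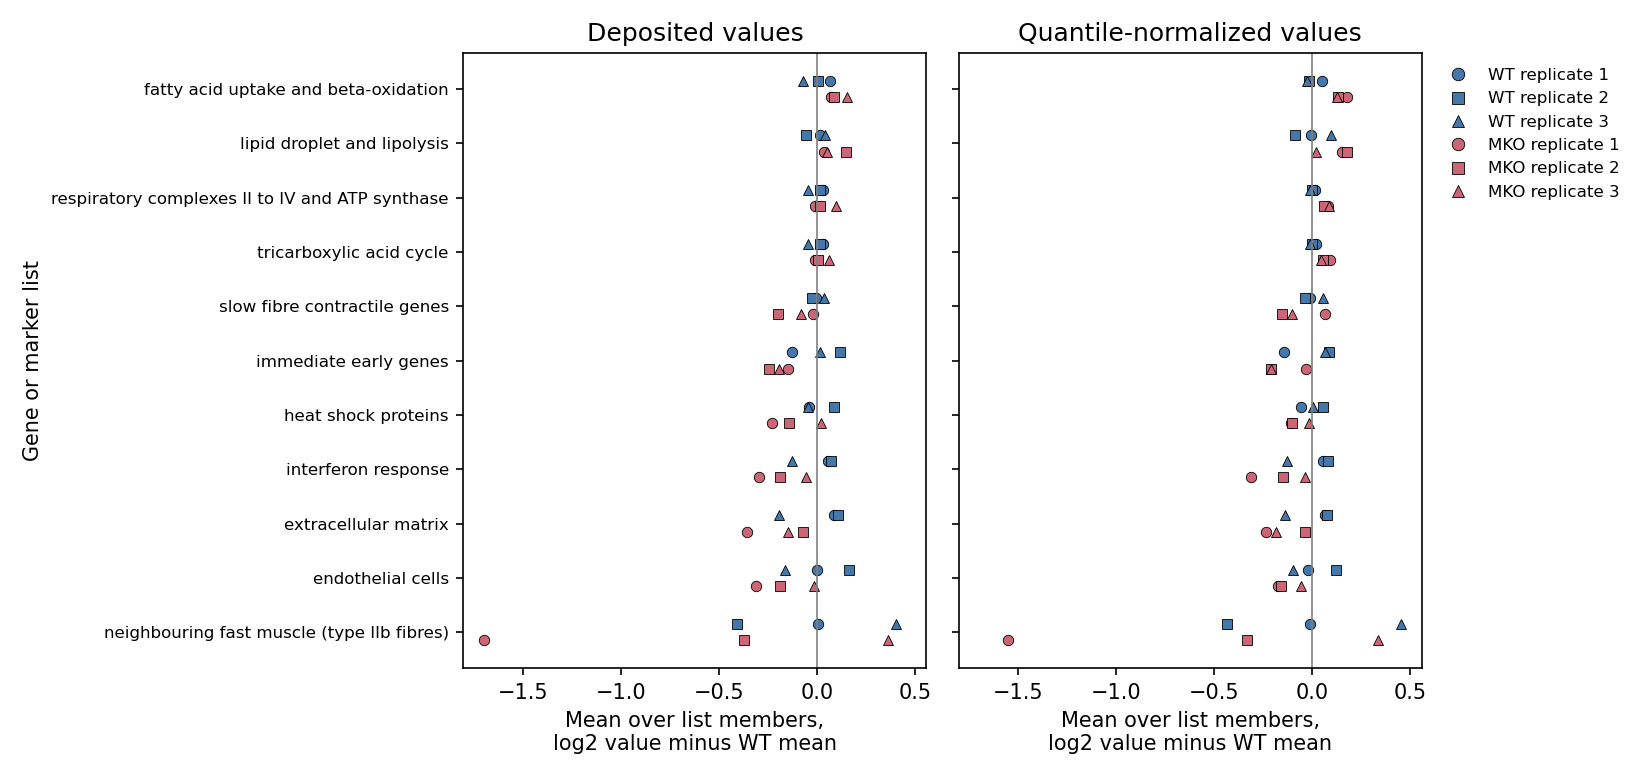
Mean over the members of each list of the log2 value minus the WT mean, per array, for deposited values (left) and after quantile normalization (right). The fatty acid list of each MKO array lay above every WT array, by at least 0.0043 in the deposited values (WT SD 0.0679) and 0.0789 after quantile normalization (WT SD 0.0415). In the deposited values the type IIb fibre markers of MKO replicate 1 lay at −1.70, against −0.41 to 0.40 in the other arrays. Also in the deposited values, WT replicate 3 lay below MKO replicate 3 for the extracellular matrix, interferon, heat shock and endothelial lists.

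The remaining gene lists described here did not pass. Circadian clock genes had a median of −0.09 (adjusted p = 0.0626), but 5 of 20 were lower when adjusted over the list alone: Gm129 (−0.59, SE 0.16), also called Ciart, Bhlhe40 (−0.50, SE 0.14), Dbp (−0.49, SE 0.15), Nr1d1 (−0.33, SE 0.10) and Bhlhe41 (−0.42, SE 0.14). In the satellite cell and regeneration list (median −0.12, adjusted p = 0.0626), Myh3 was lower over the list alone (adjusted p = 0.0109), while the stem cell factor Pax7 stood at 0.24 (SE 0.14). The targets of the transcription regulators SRF, MRTF and YAP had a median of −0.04 (adjusted p = 0.107), with Ankrd1 at −0.51 (SE 0.20), Egr1 at −0.73 (SE 0.31) and Vcl at −0.29 (SE 0.12). The calcineurin, NFAT and fibre type regulators had a median of −0.04 (adjusted p = 0.751), and the calcineurin subunit Ppp3r1 stood at 0.42 (SE 0.13). Without WT replicate 3 the SRF (adjusted p = 0.0161) and clock (0.0321) lists passed as lower, as did the clock list without MKO replicate 3 (0.0241) and the SRF list without MKO replicate 2 (0.0476). The clock list also passed with the replicate block (0.0491) and with robust moderation (0.0343). Over their alternatives the highest adjusted p was 0.740 for the SRF list and 0.381 for the clock list.

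Among metabolic lists, lipid synthesis had a median of −0.13 (adjusted p = 0.0626), with Scd2 at −0.43 (SE 0.13) and Fads2 at −0.45 (SE 0.17). Of the 10 Fads2 probe sets, 17362599 stood at −3.59 (SE 0.46). Glycolysis and glycogen genes had a median of −0.06 (adjusted p = 0.0626), with Pkm at −0.20 (SE 0.08). Lipid synthesis passed as lower without MKO replicate 2 (adjusted p = 0.00969, up to 0.604 over its alternatives) and glycolysis without WT replicate 1 (0.0336), WT replicate 3 (0.0306) or MKO replicate 3 (0.00618, up to 0.923). Glucose uptake and insulin signalling genes had a median of −0.02 (adjusted p = 0.774), with Foxo1 at 0.33 (SE 0.11), Tbc1d4 at 0.41 (SE 0.16) and Prkaa1 at −0.31 (SE 0.12). The list of FoxO, proteolysis and autophagy had a median of 0.04 (adjusted p = 0.414), with Ddit4 at 0.50 (SE 0.20) and Atg12 at −0.34 (SE 0.11), and passed as higher with bright probe sets only (0.0326). Denervation and neuromuscular junction genes had a median of −0.03 (adjusted p = 0.237), with the myogenic factor Myog at −0.51 (SE 0.14). Myokines and secreted factors had a median of −0.10 (adjusted p = 0.134), with Apln at −0.59 (SE 0.23) and Fam132b, the iron-regulating hormone erythroferrone, at 0.40 (SE 0.16). The unfolded protein and integrated stress response (−0.06, adjusted p = 0.204), antioxidant defence (0.01, adjusted p = 0.611) and cytosolic ribosomal proteins (−0.07, adjusted p = 0.0595) did not pass. The ribosomal list was the 1 list that the self-contained test fry called (adjusted p = 0.0386).

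Marker lists of non-muscle cells went both ways. Of 12 marker lists, 5 were lower and 1 higher, 2 lower and 0 higher after quantile normalization, and 0 in either direction with an estimated correlation or without MKO replicate 1. Endothelial markers had a median of −0.10 (12 of 13 lower, adjusted p = 0.00429, adjusted p = 0.565 with an estimated correlation), and Cldn5 was lower over the list alone (adjusted p = 0.00413). The arrays overlapped in the endothelial list mean, with WT replicate 3 (−0.16) below MKO replicate 3 (−0.02) in the deposited values. Markers of fibroblasts and fibro-adipogenic progenitors had a median of −0.20 (11 of 12 lower, adjusted p = 0.00973, adjusted p = 0.565 with an estimated correlation), with Pdgfra at −0.34 (SE 0.14), Lum at −0.39 (SE 0.20) and Col1a1 at −0.31 (SE 0.16). Macrophage and monocyte markers had a median of −0.12 (11 of 12 lower, adjusted p = 0.0323, 0.565 with an estimated correlation), with Cd68 at −0.82 (SE 0.26), and tenocyte markers one of −0.12 (8 of 9 lower, adjusted p = 0.0323, 0.578 with an estimated correlation), with Thbs4, Chad (−0.34, SE 0.18) and Tnmd (−0.37, SE 0.21). Smooth muscle and pericyte markers had a median of −0.08 (9 of 12 lower, adjusted p = 0.0354, 0.565 with an estimated correlation). Of these, Des, which muscle fibres also express, was lower over the list alone (−0.23, SE 0.06, adjusted p = 0.0403). T and B lymphocyte markers had a median of 0.12 (8 of 9 higher, adjusted p = 0.0323, 0.565 with an estimated correlation), with Cd3g at 3.19 ± 0.18 in MKO against 2.78 ± 0.15 in WT (SD, n = 3), in the lower part of the range of values. The median of the endothelial markers was −0.04 without MKO replicate 1 and −0.04 without WT replicate 2, and that of the lymphocyte markers 0.01 in each case.

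The marker calls also rested on other arrays. Without WT replicate 2 the endothelial (adjusted p = 0.198), smooth muscle (0.109), tenocyte (0.301) and lymphocyte (0.143) lists did not pass. Without WT replicate 1 the fibroblast (0.247), smooth muscle (0.246), macrophage (0.323), tenocyte (0.453) and lymphocyte (0.125) lists did not. Without MKO replicate 3 the smooth muscle (0.193) and macrophage (0.110) lists did not, and without MKO replicate 2 the tenocyte list did not (0.0551). Over their alternatives the highest adjusted p of the 6 lists was 0.614 to 0.621 and the lowest 5.41e-07 to 0.0156. Adipocyte markers (median 0.03, adjusted p = 0.493), brown adipocyte markers (0.01, adjusted p = 0.493), neutrophil and mast cell markers (0.09, adjusted p = 0.131), Schwann cell and nerve markers (0.08, adjusted p = 0.472) and satellite cell markers (−0.07, adjusted p = 0.976) did not pass. Type IIb fibre markers, a sign of neighbouring fast muscle, had a median of −0.40 (adjusted p = 0.106), with MKO replicate 1 at −1.70, replicate 2 at −0.37 and replicate 3 at 0.36 from the WT mean. They passed as lower without WT replicate 2 (adjusted p = 0.00907) or MKO replicate 3 (0.000174) and with the replicate block (0.0138), Schwann cell and nerve markers passed as higher for the median of probe sets (0.0142), and neutrophil and mast cell markers passed as higher without MKO replicate 3 (0.0253). The 2 measured erythroid markers, Alas2 and Slc4a1, stood at −0.47 (SE 0.27) and −0.27 (SE 0.20).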

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

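Quantile normalization without MKO replicate 1, quantile normalization with an estimated correlation and the restriction to bright probe sets were chosen after seeing the data. The values for single genes, probe sets and lists were compared under all alternatives, besides the Gna13 mean and probe set 17257825 given below. Of these values, 130 lost the threshold and 37 gained it. The fast fibre values that changed sign, given next, also lost it and are not among the 130. Of values past the threshold, the median of the fast fibre list changed sign without MKO replicate 1 (0.0313, in a range from −0.161 with an array left out, and 0.0482 with quantile normalization), as did that of the slow fibre list without MKO replicate 2 (0.0054, its test still pointing down), and each lost the threshold. Of values not past it in either setting, 34 list medians, 17 values of genes and 1 probe set changed sign. Among them were Gna13 probe set 17257826 (−0.0188) and Pvalb (from −0.64 to 0.0665) by the LPE test. The LPE values are differences of group medians, while the limma values are differences of group means. Others were Psmb2 (from −0.43 to 0.379) with the median of probe sets and the glucose uptake list (from −0.02 to 0.0421) with quantile normalization. The cause was not tested unless named here, and array signal over background is not given in the table.

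Genes past an adjusted p of 0.05, 0 in either direction, became 7 higher and 16 lower by the LPE test and 1 lower (Rrad) with array weights. With each array left out in turn they ranged from 0 to 1 higher and from 0 to 1 lower. At an unadjusted p under 0.05, the 444 higher genes became 805 with array weights, 129 for genes above the median level and 294 with bright probe sets (fewer genes tested), 719 with quantile normalization without MKO replicate 1, and 5925 of all rows, which are more numerous than genes. They ranged from 300 to 607 with an array left out. The 558 lower genes became 1000 with array weights, 354 with median centring, 371 for genes above the median level and 7552 of all rows, and ranged from 393 to 975.

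The Gna13 mean, 0.04, ranged from −0.0571 (without WT replicate 1) to 0.138 with an array left out and was 0.65 for the median of its probe sets. It was −0.0282 without MKO replicate 3. Probe set 17257825, at −1.95, ranged from −2.19 to −1.67 with an array left out and had an adjusted p of 0.977 over all rows because far more rows were tested.

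The 2 rising gene lists became 1 without a variance trend, 5 with quantile normalization, 4 for genes above the median level, 4 with bright probe sets, and 0 with an estimated correlation, with fry or with quantile normalization and an estimated correlation, ranging from 1 to 2 with an array left out. The 8 falling gene lists became 5 without a variance trend, 4 with quantile normalization, 5 with the median of probe sets, 3 with quantile normalization without MKO replicate 1, 0 with an estimated correlation, 1 with fry and 0 with quantile normalization and an estimated correlation, ranging from 3 to 11. The 1 rising marker list became 0 with quantile normalization, for genes above the median level, with bright probe sets, with quantile normalization without MKO replicate 1, with an estimated correlation, with fry and with quantile normalization and an estimated correlation, ranging from 0 to 2. The 5 falling marker lists became 3 without a variance trend, 2 with quantile normalization, 2 for genes above the median level, 2 with the median of probe sets, 1 with bright probe sets, and 0 with quantile normalization without MKO replicate 1, an estimated correlation, fry or quantile normalization and an estimated correlation, ranging from 0 to 5. For genes above the median level the mean correlations were 0.982 within WT, 0.974 within MKO and 0.978 between groups.

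Deviations of same-numbered arrays from their group means correlated at −0.0881, 0.0907 and −0.236 across genes. Differently numbered arrays correlated at −0.226 to 0.296. The values gave no sign that the replicate numbers pair the mice, but they cannot exclude it. With the replicate number as a block, 0 genes passed the adjusted threshold in either direction, 399 were higher and 474 lower at an unadjusted p under 0.05, and 2 gene lists were higher and 9 lower.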

Other observations

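Of the genes above the median level whose arrays did not overlap at an unadjusted p under 0.01, 98 were lower in MKO and 23 higher, and after quantile normalization 92 were lower and 54 higher. None passed the adjusted threshold, and the genes named in this paragraph were chosen after their values were seen. Among the lower ones, Wdr1, a partner of cofilin in actin turnover, differed by −0.36 (SE 0.09), Palld, an actin-bundling scaffold, by −0.48 (SE 0.12), Evl, an actin elongation factor, by −0.53 (SE 0.14) and the fibronectin receptor subunit Itga5 by −0.48 (SE 0.13). The nonmuscle myosin Myh10 differed by −0.32 (SE 0.10). Others were the sarcomere gene Ldb3 at −0.22 (SE 0.07), Pdlim1 at −0.25 (SE 0.07), Kbtbd5 (now Klhl40), a stabiliser of thin filament proteins, at −0.55 (SE 0.15) and the repair protein Trim72 at −0.30 (SE 0.08). Among the higher ones were Pank1, an enzyme of coenzyme A synthesis (0.41, SE 0.11), and Bcl2l1 (0.46, SE 0.15).

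The 10 genes nearest to Gna13 in the RefSeq gene order of assembly GRCm38.p6, by name only, had no member past an unadjusted p of 0.05.

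Of the tests in the paragraphs below, those on level-dependent shifts of the gene lists, on the 4 and the 5 falling lists taken separately, on type IIb muscle, on adipocytes and on iron genes with Fam132b added were chosen after the result was seen.

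More gene lists fell (8) than rose (2) at camera's preset correlation, while 0 passed in either direction at an estimated one. A level-dependent difference between arrays may account for this excess of falls. The median MKO minus WT difference went from 0.068 in the dimmest 10% of genes to −0.0405 at high levels. After quantile normalization 4 lists fell and 5 rose, so the excess was gone. The 4 that fell (extracellular matrix, immediate early, interferon and heat shock genes) were chosen because they also passed after quantile normalization. Their largest camera adjusted p there, 0.0241 at the preset correlation, was therefore fixed by that choice and cannot weigh this trend as their cause. At an estimated correlation it was 0.337 for each, and none passed. Their medians went, in that order, from −0.220, −0.159, −0.185 and −0.106 to −0.177, −0.126, −0.170 and −0.0578. MKO replicate 1 alone is argued against as the cause of every fall, since 3 lists (extracellular matrix, immediate early and slow fibre genes) fell at the preset correlation with quantile normalization and without that array. In that setting 3 lists also rose, so it does not argue against that array as the cause of the excess of falls. That array also had the lowest median relative to the gene means at high levels (−0.138), so it overlaps with the level-dependent difference. For the 5 other falling lists the smallest adjusted p in that setting was 0.109, and that array and the loss of an array cannot be told apart. When that array was left out, the medians of the heat shock list (−0.106 to −0.0785) and the proteasome list (−0.0885 to −0.0561) shrank in the deposited values but not after quantile normalization (−0.0578 to −0.0816 and −0.0466 to −0.0619). Those of the interferon (−0.170 to −0.0925 after quantile normalization) and the calcium handling and excitation lists (−0.062 to −0.0291) shrank in both forms, and that of the fast fibre list changed sign. The matrix list fell along with the markers of fibroblasts, with which it shares genes, and fewer such cells were not tested as its cause. The 10 splits of the 6 arrays are too few for a share under 0.05. In the deposited values the real split gave 10 lists and the highest other 11, and 2 splits, the real one included, gave at least 10. After quantile normalization the real split gave 9 and the highest other 5.

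Genes of fatty acid use were higher in MKO at the preset correlation, but not at an estimated one (adjusted p = 0.381, and 0.149 with quantile normalization). Quantile normalization raised the list's median from 0.07 to 0.113. Removing a trend that is negative at high levels raises lists of bright genes, so this increase is no separate support. The lists of respiratory complexes II to IV (0.02 to 0.06) and of the tricarboxylic acid cycle (0.02 to 0.07) moved alike. For members at high levels the trend in the deposited values (median −0.0405) runs opposite to a rise, so it would not by itself give one. Less type IIb muscle cannot be told apart from a change within the fibres. MKO replicates 2 and 3, whose IIb markers lay within the WT range, had list means at least 0.0789 above the highest WT array after quantile normalization (WT SD 0.0415), but only 0.0239 above it in the deposited values (WT SD 0.0679). Without MKO replicate 1, the array with the lowest IIb markers, the list still passed at the preset correlation (median 0.0863, adjusted p = 3.91e-05). More adipocytes cannot be told apart from such a change either. After quantile normalization the adipocyte markers stood above the WT mean in MKO replicate 2 (0.393) but not in replicates 1 (−0.0098) and 3 (−0.205). The fatty acid list means of replicates 1 and 3 (0.179 and 0.127) lay above every WT array. Adipocytes stay open because these markers differed from the WT mean by little more than the WT SD (0.190) in MKO replicate 3 and by less in MKO replicate 1. They were also as low in WT replicate 2 (−0.2095). Of the 10 splits, too few for a share under 0.05, the 1 that gave as small a p was the real one. The −log10 p was 5.86 in the real split and 5.34 in the highest other in the deposited values, and 11.2 and 5.55 after quantile normalization. A change within the muscle fibres stays an untested hypothesis.

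Gna13 itself moved in both directions, with 1 probe set lower and 3 higher in MKO. Level-dependent shifts are argued against for the 3 rising ones, since other genes' probe sets at their levels had median changes of −0.0243 to −0.0093. The central 95% of those changes ended at 0.514 or below, and each Gna13 probe set lay above 99.2% or more of its own comparison set. The 3 were picked because they rose, so their place in that tail is no separate support. Adjusted over all probe sets with 1 gene symbol, none of the 3 rises passed in limma (adjusted p = 0.979 for each). A transcript that lacks the deleted exon but accumulates may be a hypothesis, untested because the exon each probe set covers was not used here.

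Tfrc was lower and Slc40a1 and Hfe higher in MKO, and the hypothesis that iron genes changed as a group was tested on 20 other iron genes listed before that test. Of these, 0 passed an unadjusted p of 0.05 in limma, within the range of random lists of like level (up to 3 in the central 95% of lists). The count gave no sign of a broad change of iron genes. With 3 mice per group it cannot exclude a modest shared shift, and no test of a shift of the list was run. Fam132b, the hormone erythroferrone, was not on that list (0.40, unadjusted p = 0.0240), and with it the count was 1 of 21, also within the range of random lists (up to 3). At an unadjusted p under 0.05 the real split of the arrays gave 1002 genes and the highest other split 2774. Of the 10 splits, 5 gave at least 1002, the real one included, and the 10 splits are too few for a share under 0.05. The split with 2774 genes set WT replicates 1 and 2 and MKO replicate 3 against the rest, the order of the first principal component, and had 0 genes past the adjusted threshold. It points to the structure of the arrays that this component already shows, which is not that of genotype, and is no independent sign of it. Array medians relative to the gene means, at log2 levels of 6.12 to 7.04, ran in the same order. They went from 0.084 in MKO replicate 3 to −0.138 in MKO replicate 1. The gene lists called in this split went from 11 to 3 after quantile normalization. A structure of the samples therefore cannot be told apart from the level-dependent difference between arrays.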
